A study of Mus musculus with 26 samples.

How the data were processed

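Lung RNA from female MutaMouse mice was measured on 2-colour Agilent arrays. MutaMouse is a transgenic strain that carries a reporter for counting mutations in tissue DNA. Per the labels, the animals received multiwalled carbon nanotubes suspended in mouse serum by intratracheal instillation once a week for 4 weeks, and tissue was taken 56 days after the last dose. The materials were NM-401 and Mitsui XNRi-7, each at 42.7 or 128 µg per mouse, called low and high dose here. The labels do not say whether a dose is per instillation or in total. They differ over the controls, which the study design calls vehicle controls and the treatment protocol describes as gavaged with olive oil, so how the controls were treated is not settled. They also differ over sex: the sample labels say female and the design says male. In the data both Xist probes were well above background in 24 of 25 animals. Of the Y genes, Ddx3y and Kdm5d were so in 0 and Uty in 1, but the probe of the Y gene Eif2s3y was in 22. Xist, Ddx3y, Kdm5d and Uty read as female for these 24, while Eif2s3y goes the other way, and why it does was not tested.

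The 25 animals fell into 5 groups of 5: control, NM-401 low, NM-401 high, Mitsui low and Mitsui high. They were run on 26 arrays on 4 slides, because 1 Mitsui low animal was hybridised on slides 3 and 4. Its 2 arrays were averaged into 1 value per probe. On every array the animal's RNA carried Cy5 and a universal mouse reference RNA carried Cy3.

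The authors deposited a matrix of normalised log2 ratios of Cy5 over Cy3, whose method they do not name. The deposited scanner output holds median spot and background signals as intensity, without background subtraction, per the file headers. It also holds log10 ratios that Agilent Feature Extraction 11.0.1.1 made after background subtraction and dye normalisation, per the file headers. The remaining deposited columns are of another kind: flags of 0 or 1 set by Feature Extraction per the file headers, which mark outlier spots and spots well above background. Across the arrays, 45.8% to 62.1% of probes were well above background in Cy5 and 46.4% to 64.4% in Cy3. The number of animals limits the precision of every value below.

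The analysis started from the median signals, and mean signals were not used here. In R 4.3.3 with limma 3.58.1, the local background was removed by normexp with an offset of 50, and the log2 ratios of each array were normalised by loess. Spots set as outliers, 0.461% of all, were left out. Of 55681 probes, 30466 were kept because their Cy5 signal was well above background in at least 4 animals of at least 1 group. Each gene was read by its kept probe with the highest mean intensity, which left 22950 features, 14838 of them with a gene symbol and 8112 without. Symbols came from matching the RefSeq accession of a probe, as the arrays' own gene names were not used here, and 28446 probes had none.

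A linear model with 1 mean per group was fitted to all animals with limma, using empirical Bayes moderation (20 residual and 3.76 prior degrees of freedom). A feature was called when its Benjamini-Hochberg adjusted p was under 0.05. Each exposed group was compared with the control, the high with the low dose of each material, and the materials with each other at each dose, and the material by dose interaction was tested. Errors of log2 changes are standard errors from this model with n = 5 per group. A second fit with slide as a block is given beside the counts, because slide explained part of the variance of 6654 features. Array column, array row and replicate number explained it in 0 features at an adjusted p under 0.05 by limma's F test, with 574, 999 and 1265 at an unadjusted p under 0.05. Replicate numbers did not pair animals across groups.

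The groups, the comparisons, the 32 gene lists tested, the rule for naming genes and most alternatives were chosen before the data were examined. The lists hold 9 to 44 tested genes each and cover inflammation, tissue remodelling, DNA damage, metabolism, handling of the tissue and markers of lung and adjoining cell types. Each list was tested against all other features by camera with a preset correlation of 0.01, and again with an estimated correlation; fry tested whether a list's genes moved on balance one way. Genes named for an exposure are the 12 largest rises, the 6 largest falls and up to 4 called members per list. For other comparisons they are 5 each way and up to 2 per list, and where none was called, the 3 with the smallest p. Where the control lay at background in every animal, a fold is given as a lower bound, from Cy5 signals, against the dimmest signal still well above background on the control arrays or the probe's own control signal, whichever was higher.

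Alternatives covered background correction, within-array normalisation, the filter, the choice of probe, blocks for slide, array column and replicate, the variance model, the repeated array, the values from Feature Extraction and from the authors, and leaving out each animal. The blocks with array column, and median centring together with the slide block, were added after seeing the data. The model was tested on simulated data with 50 changed genes per fold. At 1.5-fold it called 82% to 88% of them and at 1.25-fold 24% to 42%. The simulated genes varied independently of each other and without slide effects, unlike the real ones, so these rates need not hold for the real data. Liver and heart, which the labels mention as collected, were not analysed here.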

Results

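The data are gene expression values from the lungs of 25 mice in 5 groups of 5, 4 of which received carbon nanotubes in 4 weekly instillations. Tissue was taken 56 days after the last dose. Each value is a log2 ratio of an animal's lung RNA over a common reference RNA, so changes are differences between groups in that ratio. The mean share of probes well above background in the lung channel was 53.8% ± 4.31 (SD) in the control, 54.5% ± 3.81 in NM-401 low, 56.6% ± 4.91 in NM-401 high, 52.5% ± 4.29 in Mitsui low (6 arrays) and 53.7% ± 4.78 in Mitsui high, with n = 5 elsewhere. The series title names pulmonary genotoxicity of multiwalled carbon nanotubes. The comparisons below ask which genes differed between exposed and control lungs, with the dose and with the material. All groups were spread over the 4 slides except NM-401 high, which had no array on slide 2. Within a slide, groups held 1 or 2 arrays each, and NM-401 high lay in array columns 1 and 2 only.

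In lungs given the low dose of NM-401, Trem2, a lipid-sensing receptor of macrophages, was 11.2-fold higher than in control lungs (95% interval 7.43 to 16.8, n = 5 per group), moving from a mean log2 ratio of -2.10 ± 0.22 (SD) in controls to 1.39 ± 0.65. The acute phase protein gene Saa3 and the neutrophil chemokine gene Cxcl5 were each 16.6-fold higher. Muc5b, a gel-forming mucin of the airways, was 8.95-fold higher. In total 3890 of 22950 features were called, 2054 higher and 1836 lower, of which 805 and 300 changed at least 1.5-fold.

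In the list of macrophage lysosome and lipid-laden macrophage genes, 26 of 31 measured members rose with NM-401 low, 1 fell and 4 were not called (27 called when adjusted over the list alone). The list median was 1.04 on the log2 scale (camera adjusted p = 1.08e-22, 0.024 with an estimated correlation). Examples were Gpnmb at 3.33 ± 0.35 (SE), Spp1, which encodes osteopontin, at 2.92 ± 0.40 and the macrophage elastase gene Mmp12 at 2.63 ± 0.26. Macrophage and monocyte markers rose in 11 of 21 genes with none falling (13 adjusted over the list alone), with a median of 0.37 (adjusted p = 4.83e-07, 0.0165 with an estimated correlation). Among acute phase reactants 15 of 20 rose and 1 fell (17 adjusted over the list alone, median 1.28, adjusted p = 2.65e-12), among them Fgg, the fibrinogen gamma chain, at 3.07 ± 0.44 and Lcn2 at 1.90 ± 0.15. Chemokine ligands had 14 of 26 rising and 2 falling (18 adjusted over the list alone, median 0.91, adjusted p = 5.91e-09), led by Cxcl5 and the monocyte attractants Ccl7 (3.47 ± 0.43) and Ccl2 (2.76 ± 0.38). Type 2 response genes had 14 of 25 rising (15 adjusted over the list alone, median 0.75, adjusted p = 2.35e-11). Within that list Clca1, secreted by goblet cells, was above background in 0 of 5 controls and 5 of 5 exposed animals, at least 69.1-fold higher, and Slc26a4, the anion exchanger pendrin, rose by 2.92 ± 0.19. Complement components rose in 13 of 21 genes (14 adjusted over the list alone, median 0.80, adjusted p = 1.79e-12), including C3 at 1.63 ± 0.13 and C1qb at 1.60 ± 0.22. Inflammatory cytokines and receptors rose in 12 of 25 (14 adjusted over the list alone, median 0.41, adjusted p = 2.33e-08), with Cd14 at 2.26 ± 0.19 and Il33 at 1.18 ± 0.20. These 5 lists also held with an estimated correlation, at adjusted p from 0.00484 to 0.0249.

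Several further lists passed in NM-401 low only with the preset correlation. Interferon-stimulated genes rose in 16 of 28 (20 adjusted over the list alone, median 1.06, adjusted p = 1.99e-09), such as the antiviral enzyme genes Oas1a (3.11 ± 0.57) and Oas2 (2.53 ± 0.52), with adjusted p = 0.324 with an estimated correlation. Their list mean was 1.95 to 2.20 in NM-401 low animals 3, 4 and 5, but 0.53 and 0.50 in animals 1 and 2, near the controls at -0.00 to 0.42. Mitotic and S-phase genes rose in 16 of 34 (16 adjusted over the list alone, median 0.28, adjusted p = 1.23e-09, adjusted p = 0.146 with an estimated correlation), for example Uhrf1 at 0.65 ± 0.10. Alveolar type 2 markers rose in 10 of 19 and none fell (12 adjusted over the list alone, median 0.35, adjusted p = 7.18e-08, adjusted p = 0.0847 with an estimated correlation). The lipid-binding gene Fabp5, which is also in the macrophage lysosome list, rose by 1.51 ± 0.21. Surfactant and lipid genes rose in 6 of 29 and fell in 2 (11 adjusted over the list alone, median 0.20, adjusted p = 0.00256, adjusted p = 0.312 with an estimated correlation), including the surfactant protein gene Sftpd at 0.43 ± 0.09. Antigen presentation genes rose in 7 of 14 (9 adjusted over the list alone, median 0.38, adjusted p = 4.6e-06, adjusted p = 0.0909 with an estimated correlation), with the invariant chain gene Cd74 at 0.73 ± 0.13. NRF2 targets and antioxidant genes rose in 13 of 31 and fell in 4 (19 adjusted over the list alone), led by Hmox1 at 0.76 ± 0.12. The list passed at adjusted p = 0.0183 (adjusted p = 0.146 with an estimated correlation), and its median of 0.11 became -0.05 under median centring.

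Falling lists in NM-401 low were alveolar type 1 markers (6 of 16 fell, 8 adjusted over the list alone, median -0.36, adjusted p = 1.45e-05) and endothelial markers (8 of 23 fell, 8 adjusted over the list alone, median -0.30, adjusted p = 1.66e-06). So were fibroblast and smooth muscle markers (10 of 23 fell and 1 rose, 12 adjusted over the list alone, median -0.22, adjusted p = 0.000524). The caveolin gene Cav1 fell by 0.54 ± 0.13, the VEGF receptor gene Flt1 by 0.83 ± 0.14 and the fibroblast receptor gene Pdgfra by 0.92 ± 0.13. With an estimated correlation these lists had adjusted p = 0.126, 0.0825 and 0.199. Immediate early and heat shock genes, which vary with how tissue is handled, fell in 7 of 16 and rose in 2 (10 adjusted over the list alone, median -0.29, adjusted p = 0.0183, adjusted p = 0.324 with an estimated correlation). Red blood cell transcripts fell in 3 of 9 (4 adjusted over the list alone, median -0.17, adjusted p = 0.0182, adjusted p = 0.324 with an estimated correlation). Cardiac muscle markers, which follow how much vessel or heart tissue lies in a sample, had a median of -0.60 with 0 of 17 called by limma (0 adjusted over the list alone, adjusted p = 0.0183, adjusted p = 0.6 with an estimated correlation). The mean of every called list lay on its side of the control mean in 5 of 5 exposed animals, except 4 of 5 for immediate early and cardiac muscle genes.

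The series title names genotoxicity, and RNA values 56 days after the last dose do not measure DNA damage or mutations. The p53 target and DNA repair lists, here and below, therefore do not answer that question. In NM-401 low, p53 target genes had 5 of 28 higher and 1 lower (8 adjusted over the list alone), with a median of 0.07 that became -0.07 under median centring (adjusted p = 0.331). The kinase gene Plk3 rose by 0.49 ± 0.11 and the proapoptotic Pmaip1 fell by 0.47 ± 0.11. DNA repair genes had 5 of 44 higher and 2 lower (7 adjusted over the list alone, median 0.06, -0.09 under median centring, adjusted p = 0.171), with the base excision enzyme gene Apex1 at 0.40 ± 0.10. Extracellular matrix genes had 4 of 35 higher and 2 lower (6 adjusted over the list alone, median 0.00, -0.03 with Feature Extraction ratios and -0.13 under median centring, adjusted p = 0.465). Profibrotic signalling genes had 5 of 29 higher and 6 lower (15 adjusted over the list alone, median -0.02, mean 0.12, camera direction up, adjusted p = 0.683). Single members rose, such as Timp1, a metalloproteinase inhibitor, at 1.57 ± 0.16 and the growth factor gene Igf1 at 2.22 ± 0.25. Club and ciliated cell markers had 2 of 21 higher and 1 lower (6 adjusted over the list alone, median 0.22, adjusted p = 0.32). Markers of other tissues had 1 of 14 higher (1 adjusted over the list alone, adjusted p = 0.72), with a mean of -0.03 and a median of 0.02 that was negative with Feature Extraction ratios (-0.23), median centring (-0.05) and the authors' values (-0.04). Outside the lists Npr3, the natriuretic peptide clearance receptor, fell by 1.53 ± 0.20. In 97.9% of the called features all 5 exposed animals lay on the same side of the control mean. Over all features, called or not, the groups did not overlap in 11.6%, against 0.794% by chance. The slide block gave 5177 calls (2624 higher), and within slides 98.0% to 99.5% of the called features kept their sign. Shares of called features with one sign, by animal, slide or alternative model, come from the same animals that gave the calls. High values follow from that selection, here and below, and lend no separate support. Under median centring in place of loess only 62 were called (52 higher and 10 lower) and the median of all features moved to -0.11. Of the 3890 features 99.7% kept their sign, with a median absolute change of 0.45 against 0.43, while the median SE went from 0.11 to 0.35. Lower features outnumbered higher ones in all 4 exposures with the authors' values (1850 of 4069, 3663 of 8034, 2262 of 4872 and 2615 of 5535 higher). This was so with Feature Extraction ratios too (1915 of 4081, 3894 of 7889, 2284 of 4841 and 2602 of 5399).

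**Figure D1:**
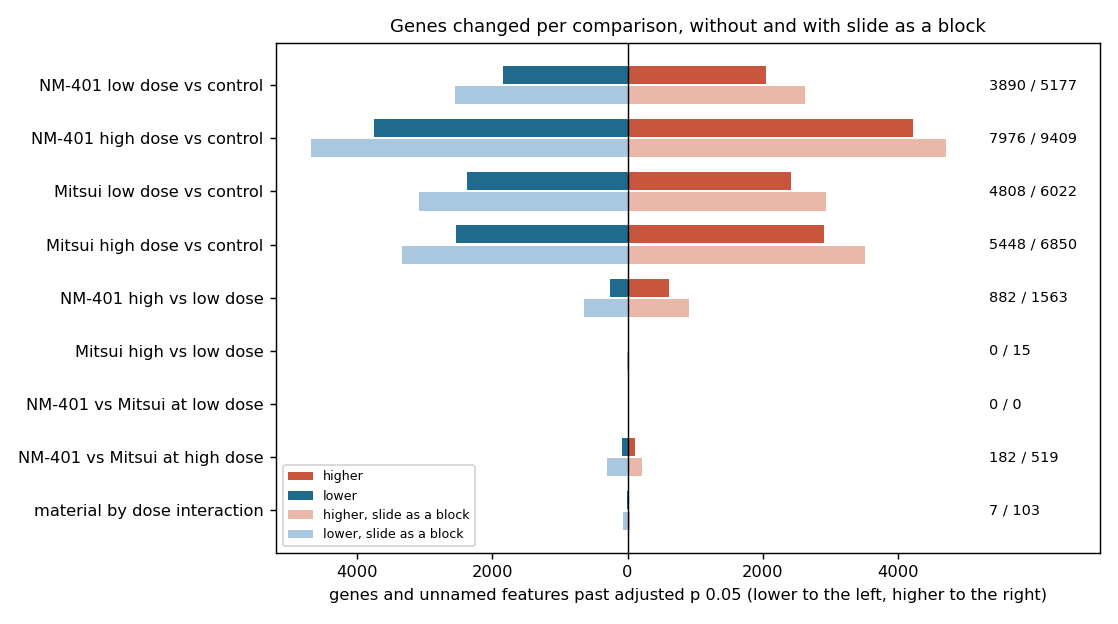
Bars give the number of features called higher and lower in each comparison (n = 5 animals per group), without and with slide as a block. NM-401 high had the most calls, 7976, and without the block the comparisons of Mitsui doses and of materials at the low dose had 0. Under median centring the 4 exposures had 62, 1064, 74 and 121 calls, most of them higher.

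The high dose of NM-401 gave the most called features of the 4 exposures. Saa3 was 49.1-fold higher than in controls (25.3 to 95.3, n = 5 per group), and the macrophage glycoprotein gene Gpnmb 33.2-fold. The monocyte chemokine gene Ccl7 was 26.8-fold higher, Spp1 26.7-fold and Trem2 25.2-fold (16.7 to 37.9). Clca1 was at least 219-fold higher and the neuropeptide gene Npy at least 26.2-fold, both above background in 0 of 5 controls and 5 of 5 exposed animals. In total 7976 features were called, 4222 higher and 3754 lower, of which 1642 and 978 changed at least 1.5-fold. The largest falls included Bex2 (-2.46 ± 0.22) and the endothelial gene Esm1 (-2.40 ± 0.29).

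Macrophage lysosome genes rose in 27 of 31 members and fell in 1 with NM-401 high (28 adjusted over the list alone, median 1.73, adjusted p = 2.99e-22, 0.0309 with an estimated correlation). Macrophage markers rose in 12 of 21 and fell in 4 (17 adjusted over the list alone, median 0.53, adjusted p = 1.04e-05), with the scavenger receptor gene Msr1 at 3.37 ± 0.30. Acute phase genes rose in 13 of 20 and fell in 1 (16 adjusted over the list alone, median 1.43, adjusted p = 5.89e-09) and chemokines in 16 of 26 with 2 falling (18 adjusted over the list alone, median 1.02, adjusted p = 3.31e-07). Inflammatory cytokines rose in 16 of 25 with 1 falling (17 adjusted over the list alone, median 0.63, adjusted p = 1.04e-07). Type 2 genes rose in 20 of 25 with 1 falling (21 adjusted over the list alone, median 0.77, adjusted p = 4.78e-09) and complement genes in 15 of 21 (16 adjusted over the list alone, median 1.07, adjusted p = 2.72e-09). Examples were the cytokine gene Il6 at 2.16 ± 0.21, Muc5b at 3.61 ± 0.25 and the complement receptor gene C3ar1 at 2.46 ± 0.21. These lists and the macrophage markers held with an estimated correlation, at adjusted p from 0.0253 to 0.033. Interferon-stimulated genes rose in 23 of 28 (25 adjusted over the list alone, median 1.43, adjusted p = 1.04e-07, adjusted p = 0.417 with an estimated correlation), with list means of 2.24 to 2.83 in animals 3, 4 and 5 but 1.07 and 0.43 in animals 1 and 2. Mitotic genes rose in 25 of 34 (29 adjusted over the list alone, median 0.44, adjusted p = 4.78e-09, adjusted p = 0.158 with an estimated correlation). Type 2 alveolar markers rose in 13 of 19 (14 adjusted over the list alone, median 0.43, adjusted p = 4e-07, adjusted p = 0.101 with an estimated correlation). Surfactant and lipid genes rose in 13 of 29 with 1 falling (16 adjusted over the list alone, median 0.30, adjusted p = 0.000242, adjusted p = 0.198 with an estimated correlation). Antigen presentation genes rose in 9 of 14 (9 adjusted over the list alone, median 0.52, adjusted p = 7.08e-05, adjusted p = 0.141 with an estimated correlation).

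Extracellular matrix genes rose in 12 of 35 and fell in 2 with NM-401 high (15 adjusted over the list alone, median 0.18, adjusted p = 0.0162, adjusted p = 0.313 with an estimated correlation). Among them were Timp1 at 2.14 ± 0.16, the collagenase gene Mmp13 at 2.12 ± 0.24 and the collagen gene Col3a1 at 0.96 ± 0.13. Profibrotic signalling genes went both ways, 10 of 29 higher and 14 lower (26 adjusted over the list alone). The median was -0.24 (0.08 under median centring), the mean 0.13 and the camera direction down at adjusted p = 0.759. Inhba, an activin subunit, rose by 1.75 ± 0.16 and Pdgfra fell by 1.38 ± 0.13. Alveolar type 1 markers fell in 13 of 16 and rose in 1 (14 adjusted over the list alone, median -0.57, adjusted p = 1.86e-06, adjusted p = 0.099 with an estimated correlation). Endothelial markers fell in 12 of 23 (12 adjusted over the list alone, median -0.44, adjusted p = 1.22e-06, adjusted p = 0.0759 with an estimated correlation). Fibroblast and smooth muscle markers fell in 13 of 23 and rose in 1 (14 adjusted over the list alone, median -0.52, adjusted p = 9.84e-06, adjusted p = 0.102 with an estimated correlation). Flt1 fell by 1.34 ± 0.14 and the stromal methyltransferase gene Inmt by 1.05 ± 0.12. Mesothelial markers fell in 8 of 16 and rose in 1 (10 adjusted over the list alone, median -0.47, adjusted p = 0.0109, adjusted p = 0.479 with an estimated correlation). Cardiac muscle markers had a median of -0.78 with 1 of 17 lower (0 adjusted over the list alone, adjusted p = 0.034, adjusted p = 0.63 with an estimated correlation). Red blood cell transcripts fell in 4 of 9 and rose in 1 (5 adjusted over the list alone, adjusted p = 0.0473, adjusted p = 0.435 with an estimated correlation), with a median of -0.32 that became 0.14 under median centring.

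The p53 target list had 7 of 28 genes higher and 4 lower with NM-401 high (12 adjusted over the list alone, median 0.08, adjusted p = 0.335). The cell cycle inhibitor gene Cdkn1a rose by 0.91 ± 0.16 and Btg2 fell by 0.63 ± 0.13. In the DNA repair list 12 of 44 were higher and 3 lower (15 adjusted over the list alone, median 0.04, -0.02 with the authors' values, adjusted p = 0.326), with Mgmt, which removes alkyl groups from guanine, at 0.67 ± 0.14. NRF2 targets had 15 of 31 higher and 9 lower (25 adjusted over the list alone, median 0.22, adjusted p = 0.0967), from Hmox1 at 1.47 ± 0.12 to the glutathione transferase gene Gsta3 at -1.57 ± 0.19. All called lists had their mean on the same side of the control mean in 5 of 5 animals, except 4 of 5 for cardiac muscle. Among the called features this held in 95.9%. Over all features the groups did not overlap in 22.5% (0.794% by chance). The slide block gave 9409 calls (4719 higher), and within slides 98.4% to 100% of calls kept their sign on slides 1, 3 and 4. Median centring left 1064 calls (951 higher and 113 lower), with the median of all features at 0.17, 93.9% of signs kept and the median SE at 0.34 in place of 0.10.

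**Figure D2:**
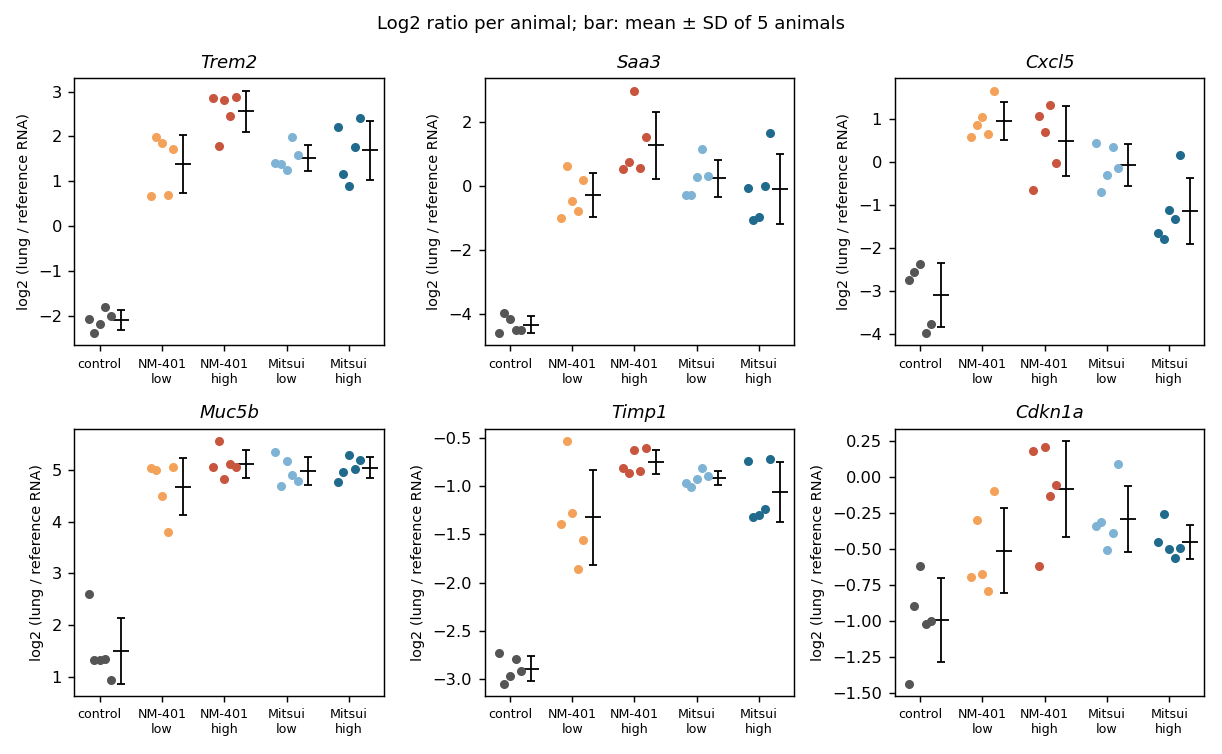
Each point is 1 animal's log2 ratio of lung over reference RNA for Trem2, Saa3, Cxcl5, Muc5b, Timp1 and Cdkn1a, with group means and SD (n = 5 per group). Trem2 lies at -2.10 ± 0.22 in controls and at 2.56 ± 0.47 in NM-401 high.

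In lungs given the low dose of Mitsui XNRi-7, Clca1 was at least 199-fold higher than in controls (above background in 0 of 5 controls and 5 of 5 exposed). Saa3 was 23.9-fold higher (12.3 to 46.5, n = 5 per group), Spp1 14.6-fold, Wfdc17 13.5-fold and Trem2 12.3-fold (8.15 to 18.5). Features called numbered 4808, 2425 higher and 2383 lower, of which 872 and 469 changed at least 1.5-fold. The acute phase gene Orm3 was among the largest falls, at -1.81 ± 0.22, unlike its list.

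With Mitsui low, 11 lists held under both correlations. Macrophage lysosome genes rose in 26 of 31 and fell in 1 (27 adjusted over the list alone, median 1.28, adjusted p = 8.76e-25) and type 2 genes in 14 of 25 (17 adjusted over the list alone, median 0.79, adjusted p = 9.47e-13). Complement genes rose in 15 of 21 (16 adjusted over the list alone, median 0.99, adjusted p = 2.18e-13) and chemokines in 16 of 26 with 2 falling (19 adjusted over the list alone, median 0.82, adjusted p = 5.45e-10). Acute phase genes rose in 13 of 20 with 1 falling (14 adjusted over the list alone, median 1.00, adjusted p = 3.75e-10). Inflammatory cytokines rose in 12 of 25 with 1 falling (13 adjusted over the list alone, median 0.32, adjusted p = 2.13e-07) and macrophage markers in 10 of 21 with 2 falling (14 adjusted over the list alone, median 0.72, adjusted p = 6.79e-07). The others were alveolar type 2 markers (15 of 19 rose, 15 adjusted over the list alone, median 0.47, adjusted p = 1.39e-12) and mitotic genes (27 of 34 rose, 30 adjusted over the list alone, median 0.46, adjusted p = 3.29e-15), with surfactant and lipid genes (18 of 29 rose, 19 adjusted over the list alone, median 0.45, adjusted p = 5.63e-09) and NRF2 targets (15 of 31 rose and 5 fell, 22 adjusted over the list alone, median 0.26, adjusted p = 0.000734). Their adjusted p ran from 0.00715 to 0.0494 with an estimated correlation. Examples were the lamellar body gene Lamp3 at 0.72 ± 0.11, the cholesterol synthesis genes Sqle (0.93 ± 0.16) and Mvd (0.90 ± 0.13), the cyclin gene Ccna2 at 0.79 ± 0.14 and the metallothionein gene Mt2 at 1.35 ± 0.19.

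Interferon-stimulated genes had a median of 0.72 in Mitsui low, with 4 of 28 higher (4 adjusted over the list alone, adjusted p = 3.5e-05, adjusted p = 0.515 with an estimated correlation). The list mean was 2.16 in animal 4, 0.90 to 1.23 in animals 1, 3 and 5 and 0.44 in animal 2, near the controls. Antigen presentation genes rose in 8 of 14 and fell in 1 (11 adjusted over the list alone, median 0.38, adjusted p = 0.000394, adjusted p = 0.186 with an estimated correlation). Alveolar type 1 markers fell in 7 of 16 (7 adjusted over the list alone, median -0.21, adjusted p = 0.0022, adjusted p = 0.271 with an estimated correlation). Endothelial markers fell in 8 of 23 (9 adjusted over the list alone, median -0.31, adjusted p = 2.15e-05, adjusted p = 0.0951 with an estimated correlation). Fibroblast and smooth muscle markers fell in 11 of 23 (13 adjusted over the list alone, median -0.25, adjusted p = 0.000394, adjusted p = 0.186 with an estimated correlation), with the endothelin receptor gene Ednrb at -1.23 ± 0.20. The p53 list had 7 of 28 higher and 2 lower (13 adjusted over the list alone, median 0.12, -0.08 under median centring, adjusted p = 0.104), including Cdkn1a at 0.70 ± 0.16. DNA repair genes had 10 of 44 higher and 2 lower (12 adjusted over the list alone, median 0.04, -0.14 under median centring, adjusted p = 0.228). Matrix genes had 7 of 35 higher and 3 lower (12 adjusted over the list alone, median 0.10, -0.10 under median centring, adjusted p = 0.0569). Profibrotic genes had 7 of 29 higher and 8 lower (19 adjusted over the list alone, median -0.03, mean 0.11, camera direction up, adjusted p = 0.897). Every called list had its mean on one side of the control mean in 5 of 5 animals, as did 98.6% of called features, and over all features the groups did not overlap in 16.1% (0.794% by chance). The block for slide gave 6022 calls (2934 higher), and 97.8% to 100% of calls kept their sign within slides. Median centring left 74 (62 higher and 12 lower), with the median of all features at -0.14, 97.3% of signs kept and the median SE at 0.34 in place of 0.10. With slide as a block as well it called 2734, of which 1059 were higher.

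In lungs given the high dose of Mitsui XNRi-7, Spp1 was 20.2-fold higher than in controls (11.5 to 35.7, n = 5 per group), Saa3 19.1-fold, Gpnmb 17.5-fold and Trem2 13.8-fold (9.17 to 20.8). Clca1 was at least 191-fold and Npy at least 11.8-fold higher, each above background in 0 of 5 controls and 5 of 5 exposed animals. The clock output gene Dbp was 4.69-fold higher and the clock gene Arntl fell by 0.99 ± 0.14. There were 5448 called features, 2915 higher and 2533 lower, of which 1047 and 431 changed at least 1.5-fold. The p53 target list passed the test here: 7 of 28 genes rose and 1 fell (10 adjusted over the list alone, adjusted p = 0.04, adjusted p = 0.148 with an estimated correlation), and its median of 0.15 became -0.05 under median centring, which moved the median of all features to -0.13. Plk3 rose by 0.65 ± 0.11 and the apoptosis gene Bax by 0.48 ± 0.09.

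Lists that held under both correlations in Mitsui high were macrophage lysosome genes (26 of 31 rose and 1 fell, 27 adjusted over the list alone, median 1.37, adjusted p = 4.31e-22) and acute phase genes (12 of 20 rose and 1 fell, 15 adjusted over the list alone, median 1.04, adjusted p = 1.16e-09). The others were chemokines (15 of 26 rose and 2 fell, 19 adjusted over the list alone, median 0.73, adjusted p = 2.78e-07), type 2 genes (14 of 25 rose, 18 adjusted over the list alone, median 0.62, adjusted p = 6.35e-10) and complement (14 of 21 rose, 15 adjusted over the list alone, median 0.74, adjusted p = 1.86e-08), at adjusted p from 0.0284 to 0.0318 with an estimated correlation. Examples were Ccl9 at 2.96 ± 0.22 and Muc5b at 3.53 ± 0.25. Inflammatory cytokines rose in 12 of 25 and fell in 1 (14 adjusted over the list alone, median 0.50, adjusted p = 5.55e-06, adjusted p = 0.0723 with an estimated correlation). Macrophage markers rose in 9 of 21 and fell in 3 (12 adjusted over the list alone, median 0.46, adjusted p = 9.87e-05, adjusted p = 0.0687 with an estimated correlation). Alveolar type 2 markers rose in 13 of 19 (16 adjusted over the list alone, median 0.44, adjusted p = 1.86e-08, adjusted p = 0.0723 with an estimated correlation). Mitotic genes rose in 20 of 34 (23 adjusted over the list alone, median 0.33, adjusted p = 6.35e-10) and surfactant and lipid genes in 15 of 29 (19 adjusted over the list alone, median 0.31, adjusted p = 4.68e-05). NRF2 targets rose in 14 of 31 with 5 falling (22 adjusted over the list alone, adjusted p = 0.0125, median 0.21, and -0.00 under median centring). These 3 lists had adjusted p = 0.148 with an estimated correlation. Antigen presentation genes rose in 6 of 14 (7 adjusted over the list alone, median 0.28, adjusted p = 0.000797, adjusted p = 0.194 with an estimated correlation). Interferon-stimulated genes rose in 4 of 28 (4 adjusted over the list alone, median 0.65, adjusted p = 0.00281, adjusted p = 0.608 with an estimated correlation). Neutrophil markers rose in 4 of 19 (4 adjusted over the list alone, median 0.11, adjusted p = 0.0397, adjusted p = 0.462 with an estimated correlation), with Ltf, which encodes lactoferrin, at 2.68 ± 0.37.

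Type 1 alveolar markers fell in 7 of 16 with Mitsui high (7 adjusted over the list alone, median -0.21, adjusted p = 0.000302, adjusted p = 0.181 with an estimated correlation). Endothelial markers fell in 8 of 23 (8 adjusted over the list alone, median -0.19, adjusted p = 0.000312, adjusted p = 0.165 with an estimated correlation). Fibroblast and smooth muscle markers fell in 9 of 23 with 3 rising (14 adjusted over the list alone, median -0.16, adjusted p = 0.00772, adjusted p = 0.322 with an estimated correlation). Mesothelial markers fell in 4 of 16 (4 adjusted over the list alone, median -0.34, adjusted p = 0.0171, adjusted p = 0.462 with an estimated correlation). Red blood cell transcripts fell in 5 of 9 (6 adjusted over the list alone, median -0.40, adjusted p = 0.0125, adjusted p = 0.308 with an estimated correlation). DNA repair genes had 6 of 44 higher and 2 lower (8 adjusted over the list alone, median 0.09, -0.11 under median centring, adjusted p = 0.124). Matrix genes had 9 of 35 higher and 1 lower (11 adjusted over the list alone, median 0.08, -0.10 under median centring, adjusted p = 0.102). Profibrotic genes had 9 of 29 higher and 5 lower (17 adjusted over the list alone, median -0.02, mean 0.18, camera direction up, adjusted p = 0.372). All called lists lay on one side of the control mean in 5 of 5 animals, as did 95.5% of called features, and over all features the groups did not overlap in 14.6% (0.794% by chance). Within slides, the mean difference from control was above 0 in 3 of 4 slides for neutrophil markers (-0.29 to 0.76) and in 1 of 4 for mesothelial markers (-0.88 to 0.28). The other called lists kept one sign in every slide. The slide block gave 6850 calls (3513 higher), and 97.3% to 99.8% of calls kept their sign within slides. Median centring left 121 (105 higher and 16 lower), with the median of all features at -0.13, 98.3% of signs kept and the median SE at 0.34 in place of 0.10.

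**Figure D3:**
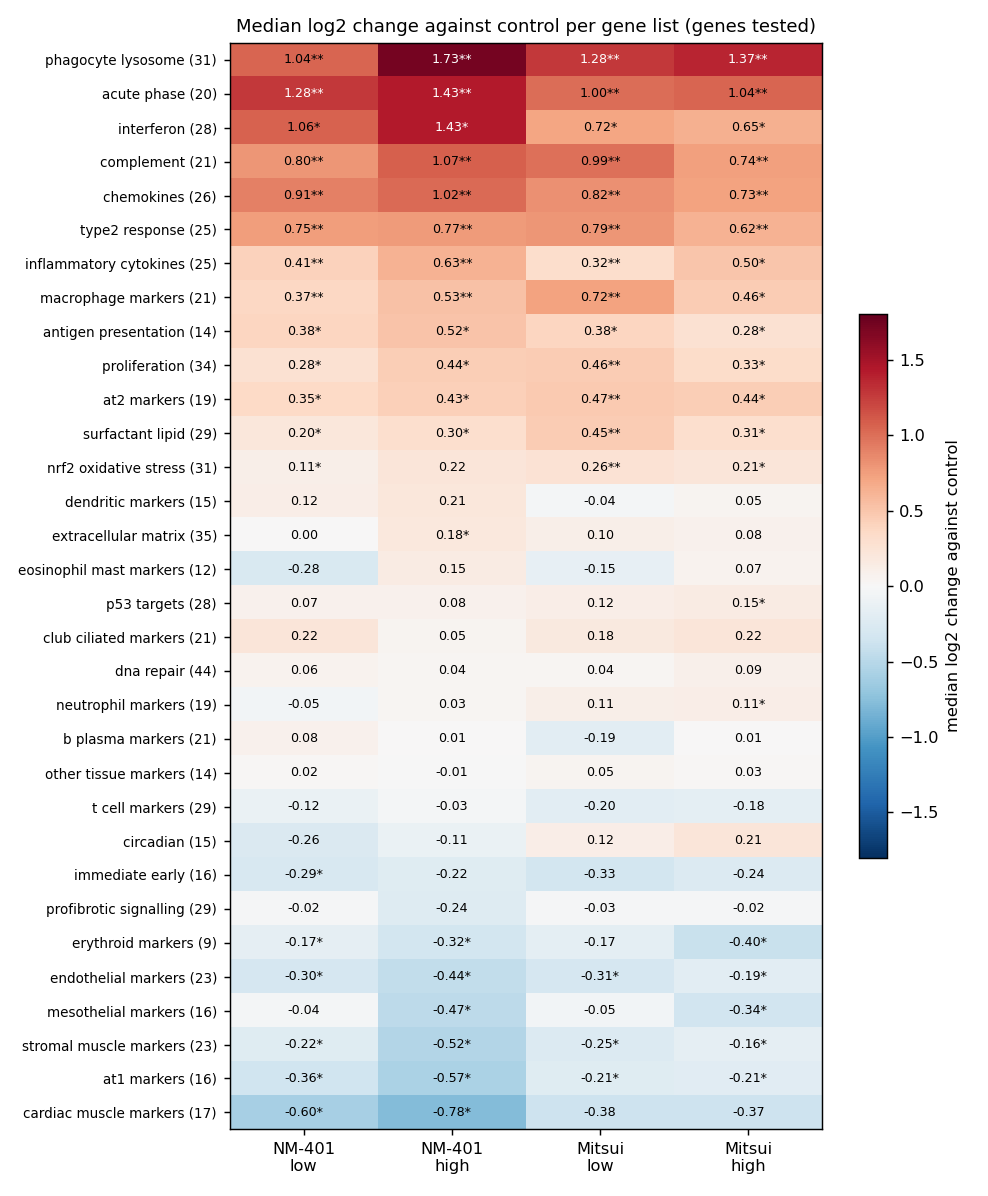
Colour gives the median log2 change against control of each of 32 gene lists in the 4 exposures (n = 5 animals per group; numbers are genes tested). Macrophage lysosome genes range from 1.04 to 1.73; under median centring the median changed sign for NRF2 targets in NM-401 low (-0.05) and Mitsui high (-0.00), for red blood cell transcripts in NM-401 high (0.14) and for p53 targets in Mitsui high (-0.05), among the lists called there. Median centring moved the median of all features to -0.11, 0.17, -0.14 and -0.13 in the 4 exposures.

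Going from the low to the high dose of NM-401, Spp1 was 3.52-fold higher at the high dose (1.99 to 6.21, n = 5 per group), and the stress response gene Atf3 2.36-fold. Gpnmb rose by 1.72 ± 0.35. Heme oxygenase Hmox1 rose by 0.70 ± 0.12 and the interleukin 1 receptor antagonist gene Il1rn by 0.97 ± 0.16, while Gsta3 fell by 1.05 ± 0.19, Esm1 by 1.41 ± 0.29 and Inmt by 0.64 ± 0.12. This comparison asks whether the response grows with the dose, and 882 features were called, 618 higher and 264 lower. Of 31 macrophage lysosome genes 17 rose (24 adjusted over the list alone, median 0.71, adjusted p = 8.42e-19, adjusted p = 0.277 with an estimated correlation). Of 35 matrix genes 4 rose (8 adjusted over the list alone, median 0.19, adjusted p = 0.000266, adjusted p = 0.284 with an estimated correlation). Of 25 inflammatory cytokines 4 rose (13 adjusted over the list alone, median 0.29, adjusted p = 0.000201, adjusted p = 0.284 with an estimated correlation). Fibroblast and smooth muscle markers fell in 4 of 23 (7 adjusted over the list alone, adjusted p = 2.23e-05, adjusted p = 0.284 with an estimated correlation), with a median of -0.27 that became 0.01 under median centring, where the median of all features was 0.30. Of 15 lists that passed, 0 did with an estimated correlation and 7 by fry, and no mitotic or interferon-stimulated gene was called by limma. In 97.8% of called features all 5 high dose animals lay beyond the low dose mean, and over all features the groups did not overlap in 3.69% (0.794% by chance). The slide block called 1563 (916 higher), and within slides 96.6% to 100% kept their sign.

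The call count for the NM-401 doses depended on the animals left out and on the model. It was 222 without NM-401 low animal 1, 183 without NM-401 low animal 4, 301 without NM-401 high animal 3 and 209 without NM-401 high animal 5. The Spp1 call was lost without NM-401 low animal 1 or NM-401 high animal 5. The authors' values gave 986 (581 higher). The count was 8 under median centring (8 higher, with the median of all features at 0.30). It was 0 when only these groups were fitted, which leaves the changes as they are and has fewer animals to estimate variance. It was also 0 with array column as a block, where NM-401 high shared only column 2 with NM-401 low. There the 882 features kept 100% of their signs and their median absolute change was 0.49 against 0.48, while the median SE went from 0.11 to 0.14.

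For Mitsui XNRi-7, no feature was called between the high and low dose by limma, with 1244 at an unadjusted p under 0.05. The smallest p were those of Gabbr1, a GABA receptor subunit, at 0.51 ± 0.10, Haus5 at 0.31 ± 0.06 and Apbb3 at 0.30 ± 0.06, each with adjusted p = 0.136 and higher in 5 of 5 animals. For 93.3% of features the 95% interval of the difference lay within 1.5-fold either way. Of 9 lists that passed, 0 did with an estimated correlation and 0 by fry, and their number was not compared with other splits of the animals. Among the 9, mesothelial markers were lowest at the high dose (0 of 16 called, 0 adjusted over the list alone, median -0.28, adjusted p = 5.37e-07, adjusted p = 0.509 with an estimated correlation). B cell and plasma cell markers were higher (0 of 21 called, 0 adjusted over the list alone, median 0.21, adjusted p = 4e-04, adjusted p = 0.509 with an estimated correlation). A block for slide called 15 features, 13 of them higher. Without Mitsui high animal 4 or 5 there were 2 or 3 calls.

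NM-401 and Mitsui XNRi-7 are both multiwalled carbon nanotubes, and at the low dose no feature was called between them by limma, with 1287 at an unadjusted p under 0.05. The 95% interval lay within 1.5-fold either way for 92.4% of features, with a median half-width of 0.20 on the log2 scale. The chaperone genes Manf and Dnajb9 had log2 differences of -0.48 ± 0.08 and -0.37 ± 0.07 (NM-401 minus Mitsui), and Tex11 -0.89 ± 0.16, each with adjusted p = 0.0819 and lower in 5 of 5 NM-401 animals. Of 11 lists that passed, surfactant and lipid genes (median -0.21, adjusted p = 8.16e-13) and clock genes (median -0.19, adjusted p = 1.24e-05) also did with an estimated correlation, each at adjusted p = 0.0316. In these lists 8 of 29 and 9 of 15 members were called when adjusted over the list alone and 0 over all features. Limma with a block for slide called 0 features, and 1977 had an unadjusted p under 0.05.

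At the high dose, single clock genes differed between the materials. Nfil3, a repressor in the clock, was 2.00-fold higher with NM-401 (1.74 to 2.30, n = 5 per group, adjusted p = 7.77e-06) and Dbp 4.83-fold lower (2.88 to 8.10, adjusted p = 0.00831), each in 5 of 5 animals. Of 15 clock genes 2 were higher and 5 lower (11 adjusted over the list alone, median -0.43, adjusted p = 0.00397, adjusted p = 0.155 with an estimated correlation). The connective tissue growth factor gene Ccn2 was lower (-0.78 ± 0.14) and the cytokine gene Il6 higher (1.01 ± 0.21, a call lost with Feature Extraction ratios). Of the genes named for this comparison, Nfil3 and Dbp kept their calls whichever animal was left out. Both calls were lost under median centring (log2 1.395 ± 0.364 and -1.633 ± 0.52, where the main values were 1.002 ± 0.0978 and -2.271 ± 0.361). The Dbp call was also lost with array column as a block (-1.999 ± 0.393), and with slide and column as blocks (-2.181 ± 0.442). In all 182 features were called, 106 higher and 76 lower with NM-401, of which 35 and 31 changed at least 1.5-fold.

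Macrophage lysosome genes were higher with NM-401 as a list (0 of 31 called, 12 adjusted over the list alone, median 0.41, adjusted p = 3.35e-10, adjusted p = 0.196 with an estimated correlation). So were interferon-stimulated genes (0 of 28 called, 0 adjusted over the list alone, median 0.87, adjusted p = 1.51e-08, adjusted p = 0.386 with an estimated correlation), where NM-401 high animals 1 and 2 had list means of 1.07 and 0.43, within or below those of Mitsui high (0.54 to 1.34), and animals 3, 4 and 5 had 2.24 to 2.83. So were inflammatory cytokines (2 of 25 higher, 9 adjusted over the list alone, median 0.25, adjusted p = 1.19e-05, adjusted p = 0.155 with an estimated correlation). Fibroblast and smooth muscle markers were lower with NM-401 (1 of 23 lower, 8 adjusted over the list alone, median -0.25, adjusted p = 6.34e-06, adjusted p = 0.155 with an estimated correlation), though 0.14 under median centring, which moved the median of all features to 0.33. The p53 list did not pass between materials (0 of 28 called, 0 adjusted over the list alone, median -0.06, 0.35 under median centring, adjusted p = 0.236). DNA repair genes did not either (0 of 44 called, 1 adjusted over the list alone, median -0.01, 0.03 with Feature Extraction ratios and 0.36 under median centring, adjusted p = 0.841). Of 14 lists that passed, 0 did with an estimated correlation and 9 by fry. Over all features the groups did not overlap in 2.67% (0.794% by chance). The slide block called 519 (220 higher), and within slides 1, 3 and 4 99.1% to 100% of the features called without the block kept their sign. They were chosen on these same arrays, so the kept signs lend no separate support.

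The count between materials at the high dose moved with single animals: 83, 915, 9 and 26 without NM-401 high animals 1, 2, 3 and 5, and 6, 7, 44 and 899 without Mitsui high animals 2, 3, 4 and 5. It was 39 with Feature Extraction ratios (17 higher) and 262 with the authors' values (110 higher). It was 0 under median centring (median of all features at 0.33), 1 with array column as a block and 4 when only these groups were fitted. With the column block the 182 features kept 100% of their signs, with a median absolute change of 0.52 against 0.51 and a median SE of 0.13 against 0.11.

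**Figure D4:**
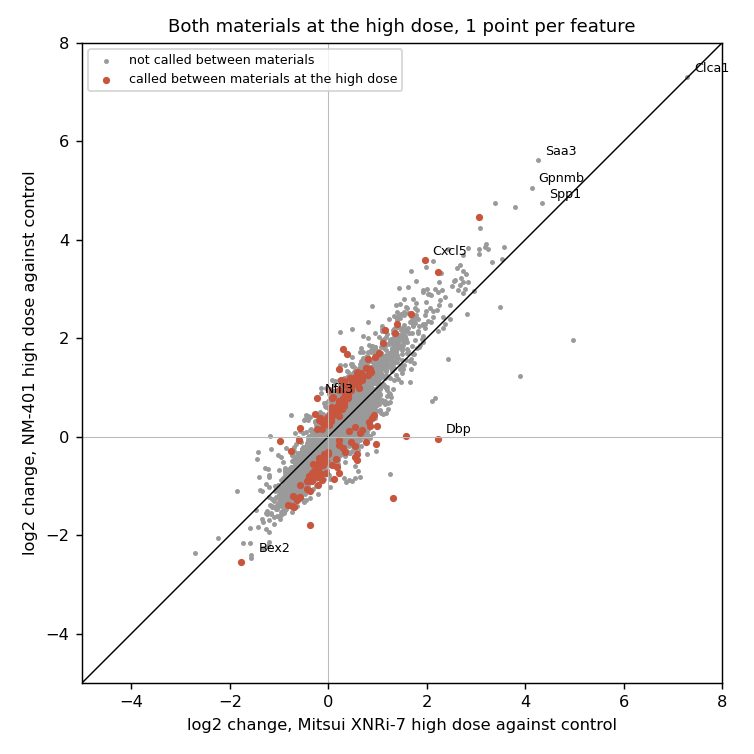
Each point is 1 feature, with its log2 change against control in Mitsui high on the x axis and in NM-401 high on the y axis (n = 5 animals per group); red points are the 182 called between the materials. Most features lie along 1 line (Pearson r 0.897), and Dbp and Nfil3 lie off it.

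Across the 22950 features the log2 changes against control of the materials at the high dose correlated with r = 0.897, where simulated data with no effect but the shared controls gave 0.499 (covariance 0.147 and 0.00881). With the controls split between the materials r was 0.711 to 0.838 over 10 splits. Genes are not independent replicates. The slope of Mitsui on NM-401 changes was 0.696 at the high dose and 0.931 at the low dose. Both materials called 2407 features higher at the high dose, against 536 if calls were independent, and 2162 lower, against 414. Calls against the same controls are not independent, so part of the excess may come from the controls. In all 4 exposures 1427 features were higher and 1318 lower, and 1 feature was called both ways among the 9314 called in at least 1.

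A test of the material by dose interaction asked whether the dose step differed between materials. It called 7 features, 5 of them with a positive difference (the signed step of NM-401 minus that of Mitsui), with 2925 at an unadjusted p under 0.05. Among them were Anxa4, a phospholipid-binding annexin, at 0.91 ± 0.16 and the endoplasmic reticulum chaperone genes Manf at 0.70 ± 0.11 and Hspa5 at 0.60 ± 0.11, calls that were lost when single animals were left out. From the low to the high dose the mean of Hspa5 rose from 0.18 to 0.55 with NM-401 and fell from 0.58 to 0.36 with Mitsui. Manf rose from -0.66 to -0.19 and fell from -0.175 to -0.40, so in both genes the steps of the means went opposite ways. No feature was called between the Mitsui doses, so a fall of these genes with the Mitsui dose is not established. Macrophage lysosome genes had a larger step in NM-401 as a list (0 of 31 called, 19 adjusted over the list alone, median 0.65, adjusted p = 7.94e-14, adjusted p = 0.177 with an estimated correlation). Of 15 lists that passed, 0 did with an estimated correlation and 3 by fry. The slide block called 103 features (30 higher). The authors' values gave 14 (8 higher), values without background correction 11 (6 higher), and median centring 0, with the median of all features at 0.27.

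**Figure D5:**
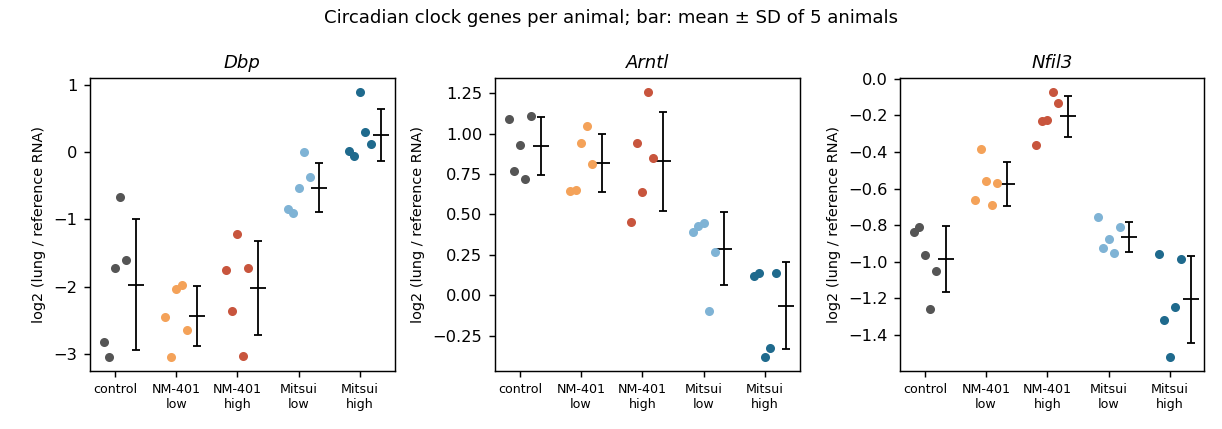
Points are the log2 ratio of lung over reference RNA of the clock genes Dbp, Arntl and Nfil3 in each animal, with group means and SD (n = 5 per group). Dbp lies at 0.26 ± 0.39 in Mitsui high and at -2.02 ± 0.70 in NM-401 high, with controls at -1.97 ± 0.97.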

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

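Chosen after their results were seen were the tests of the hour of day for the clock genes and, for Gm15772, of a response to exposure and of both levels within slides. The number of called features was compared with refits on 100 splits of the same animals. For each exposure against control 1 of 100 splits, the real one, gave as many features: NM-401 low (3890, highest other 572), NM-401 high (7976, 2491), Mitsui low (4808, 751) and Mitsui high (5448, 1663). The highest other counts lay well below the real ones, which argues against chance. It does not exclude chance, as 1 of 100 is the smallest share these splits can give and was not adjusted for the number of comparisons. Few splits gave as many for the NM-401 doses (2 of 100, 882 against a highest other of 1166), the materials at the high dose (4 of 100, 182 against 1012) and the interaction (3 of 100, 7 against 297). Chance is not excluded for these 3 either, as the split counts were not adjusted for the number of comparisons. There, other splits called more than the real one, several times more for the last comparisons. Such splits point to some structure among the samples, and what it follows was not tested. The splits did not keep slides together, and these 3 counts ran from 183 to 1232, 6 to 915 and 1 to 197 with 1 animal left out, so they are less secure than those against control. Limma called 0 features for the Mitsui doses and the materials at the low dose (1244 and 1287 at an unadjusted p under 0.05). Any split gives as many as 0, so the counts of 100 of 100 (highest other 6 and 42) decide nothing there.

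For the number of gene lists that passed, chance could not be excluded. As many lists passed in 13 of 100 splits for NM-401 low (19, highest other 21), 16 for NM-401 high (19, 21), 35 for Mitsui low (16, 22), 6 for Mitsui high (20, 22), 23 for the materials at the low dose (11, 17) and 11 at the high dose (14, 17).

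Of 165 sets of 5 animals examined, 8 held an animal far from the others, and chance marks about 1 in 20 such groups. The largest gap was in Xist, the RNA that silences an X chromosome in females, which read -3.04 in NM-401 high animal 2 against 0.41 to 0.69 in the other 4. A male animal under a wrong label is argued against by the Y chromosome genes Ddx3y, Kdm5d and Uty, with a mean of -1.26 in this animal and -1.41 to -0.78 in the other 24. A failed array or spot is argued against too, since 59.7% of probes were well above background (45.8% to 62.1% on the others) and both of 2 Xist probes lay below all other animals. Genes that escape X inactivation, Kdm6a, Kdm5c, Eif2s3x and Ddx3x, had a mean of -0.0838 against 0.38 to 0.64 in the other 24, so a single X chromosome is a candidate explanation. These means take 1 probe per gene. The Ddx3x probe in the mean lay within the range of the others (0.641, others 0.632 to 1.38), as did a second probe of Kdm5c outside it (-0.049, others -0.291 to 0.151). Second probes of Ddx3x (0.066, others 0.144 to 0.827) and Eif2s3x (-1.78, others -1.51 to -0.94) lay below all others.

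Other animals far from their group were control 2 for the extracellular matrix list mean (-0.49, others -0.39 to -0.37), Mitsui high 2 for p53 targets (-0.11, others -0.20 to -0.18), control 3 for NRF2 targets (0.60, others 0.52 to 0.54), NM-401 low 2 for surfactant and lipid genes (1.93, others 1.71 to 1.76), control 2 for alveolar type 2 markers (4.08, others 4.30 to 4.38), Mitsui low 4 for fibroblast and smooth muscle markers (2.00, others 2.12 to 2.17) and NM-401 low 5 for Xist (0.77, others 0.41 to 0.46).

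Clock genes differed between the materials at the high dose, with a mean log2 difference of -1.05 ± 0.18 over 6 genes that peak with Dbp, 5 of them called. A difference between slides is argued against, since with slide as a block 105.7% of the difference was kept (-1.11 ± 0.20, 4 called). Hour of tissue collection is a candidate explanation. Within groups, the Dbp-phase mean went down where the mean of 4 Arntl-phase genes went up (r = -0.557 over 25 animals, permutation p = 0.00356 in 1e+05 resamples, -0.532 without the 2 farthest animals). In slides 1, 2 and 3 r was -0.765, -0.690 and -0.592, and it was not computed in slide 4, which held too few animals. With group means removed, r shows that the 2 sets of genes moved opposite ways. It cannot tell the hour from another cause of a clock shift. The labels give no hour, so an effect of the material on the clock stays open, as untested.

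The dose step differed between materials in 7 features by the interaction test. The largest was Gm15772 at -4.36 (adjusted p = 0.0124), a gene outside the naming rule that was picked after its values were seen. It read at 2 levels, above -1 in 2 control, 4 NM-401 low, 0 NM-401 high, 0 Mitsui low and 5 Mitsui high animals. A response to exposure alone is argued against by the controls, which span 3.20, from -3.07 to 0.13. A slide difference as the whole cause is argued against, since 4 of 4 slides held animals at both levels (slide explains 24.9% ± 19.6 of the variance). A sequence variant stays open, because only 1 other feature reached an absolute r over 0.9 (0.937).

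The other interaction differences were Manf at 0.70 (adjusted p = 0.0332), Dock6 at -0.69 (0.0335), and Hspa5 at 0.60, Anxa4 at 0.91, Dnajb9 at 0.53 and 1 feature without a symbol at 0.50, each with adjusted p = 0.0381.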

How the results depend on the processing

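Array column as a block, alone or with slide, and median centring with slide as a block were tested only after the data had been seen. Under the other alternatives except median centring, alone or with slide as a block, the 4 counts against control stayed within 1.5 times their value. Leaving out 1 animal gave 2923 to 3883 for NM-401 low, 6943 to 7746 for NM-401 high, 4002 to 4737 for Mitsui low and 4407 to 5449 for Mitsui high. It gave 0 to 0 for the materials at the low dose. The correlation between materials ran from 0.866 to 0.908. The lists that passed ran from 18 to 20, 17 to 19, 16 to 20 and 18 to 23 for these exposures, and from 10 to 15 and 13 to 17 for the materials at the low and high dose.

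Median centring in place of loess called 62, 1064, 74 and 121 features for NM-401 low, NM-401 high, Mitsui low and Mitsui high, 8 for the NM-401 doses, 0 for the materials at the high dose and 0 for the interaction. The correlation was 0.828. With slide as a block as well, it called 1748 (1112 higher), 2734 (1059 higher) and 3024 (1580 higher) for NM-401 low, Mitsui low and Mitsui high, and 5941 for NM-401 high. It called 336 for the NM-401 doses, 23 for the materials at the high dose and 0 for the interaction. The median SE of the main NM-401 low calls was 0.35 under median centring and 0.13 with the slide block as well. Part of the spread left by median centring thus lay between slides. Fancb (0.00493) and Sec14l3 (0.0331) between the NM-401 doses and Acta2 (0.0198) between materials changed sign under median centring. Feature Extraction ratios reversed Cidec in NM-401 low (0.0901) and Tek (0.0741) and Cyp4b1 (0.0930) in Mitsui low. They called 1 feature for the materials at the low dose, 39 at the high dose and 16 for the interaction. Beyond the spread between slides, the cause was not tested for any of these.

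Fewer features were called higher than lower in Mitsui low with probes well above background on every array (2286 of 4629), the mean of a gene's probes (2441 of 4905), the first of the repeated arrays (2390 of 4945), slide as a block (2934 of 6022), array column as a block (2096 of 4222), column with slide (2720 of 5643) and median centring with slide. The same held without control 2 or 3 (2109 of 4286 and 2310 of 4737) or Mitsui low 3 (2036 of 4169), and in NM-401 low without its animal 3 or 4 (1672 of 3480 and 1928 of 3883).

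Slide as a block raised the NM-401 doses to 1563, the Mitsui doses to 15, the materials at the high dose to 519 and the interaction to 103. Array column as a block left 0, 1 and 1 for the NM-401 doses, the materials at the high dose and the interaction, and with slide as well 0, 7 and 4, and 7 for the Mitsui doses. Fitting only the groups compared left 0 for the NM-401 doses, 1 for the Mitsui doses, 1 and 4 for the materials at the low and high dose and 2 for the interaction, with fewer animals to estimate variance. Without the filter 94 were called for the materials at the high dose and 3 for the interaction, with more features tested. The interaction had 11 without background correction, 12 with probes well above background on every array, 1 with a replicate block, 4 with a trended and robust variance and 14 with the authors' values. The Mitsui doses had 1 with a replicate block. Lists that passed numbered 7, 7 and 5 for NM-401 low, NM-401 high and Mitsui high with an estimated correlation, and 2 and 0 for the materials at the low and high dose. Unless stated, the cause was not tested. Quantile scaling of mean intensities between arrays left the ratios as they were and tests nothing.

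The NM-401 dose count ran from 183 to 1232 with 1 animal left out: 222 without NM-401 low 1, 183 without NM-401 low 4, 301 without NM-401 high 3 and 209 without NM-401 high 5. The Mitsui dose count ran from 0 to 3 (2 and 3 without Mitsui high 4 and 5). Between materials at the high dose it ran from 6 to 915: 83, 915, 9 and 26 without NM-401 high 1, 2, 3 and 5, and 6, 7, 44 and 899 without Mitsui high 2, 3, 4 and 5. The interaction ran from 1 to 197: 1, 38, 11, 1 and 29 without NM-401 low 1 to 5, 3, 1, 1, 40 and 2 without NM-401 high 1 to 5, 1 without Mitsui low 1, 4 or 5, and 26, 3, 2, 1 and 197 without Mitsui high 1 to 5.

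Over the 555 values of named genes, some of them not called in the main fit, median centring ended the call of 404 and left the outcome of 148 the same. Slide as a block left that of 544 the same. The same outcome means called with the same sign in both fits, or called in neither. Signal limits what can be read, since 45.8% to 62.1% of probes per array were well above background in the lung channel.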

Other observations

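The permutation test of the endoplasmic reticulum genes was chosen after the result of fry was seen. Lists of immune cell markers other than macrophages and neutrophils did not pass against control in any exposure. For T and NK cell markers the medians over 29 genes were -0.12, -0.03, -0.20 and -0.18 in NM-401 low, NM-401 high, Mitsui low and Mitsui high (adjusted p = 0.297, 0.921, 0.14 and 0.131), with 0.19 in NM-401 high under median centring, where the mean was 0.04 and the test pointed down. B cell and plasma cell markers (21 genes) had medians of 0.08, 0.01, -0.19 and 0.01 (adjusted p = 0.168, 0.335, 0.432 and 0.372), where the authors' values gave -0.03 in NM-401 high and -0.01 in Mitsui high, and median centring -0.07 in the latter. Dendritic cell markers (15 genes) had medians of 0.12, 0.21, -0.04 and 0.05 (adjusted p = 0.515, 0.299, 0.838 and 0.678), with -0.04 in Mitsui high under median centring. Eosinophil and mast cell markers (12 genes) had medians of -0.28, 0.15, -0.15 and 0.07 (adjusted p = 0.171, 0.921, 0.139 and 0.723), and in both high dose groups the test pointed down while the means were 0.01 and -0.03. The list mean lay on the side of the test's direction in 2 to 5 of 5 animals.

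The endoplasmic reticulum chaperone genes Hspa5, Manf and Dnajb9 were among those with the smallest p between the materials at the low dose, although 0 features were called there by limma (1287 at an unadjusted p under 0.05). A hypothesis was that genes of this kind were lower as a group in NM-401 low than in Mitsui low. It was written after these genes were seen to rank high in the same comparison. The mean log2 ratio of Hspa5 was 0.10 in controls, 0.18 in NM-401 low and 0.58 in Mitsui low, and that of Manf -0.62, -0.66 and -0.175. In both genes NM-401 low lay near the controls and Mitsui low above them. Over 18 other genes of such a list the median log2 difference was -0.17, 16 of 18 lay below 0 (-0.31 to 0.10), with 0 of the 18 called. Fry gave 2.15e-05, and an exact permutation of the 10 animals gave p = 0.00794, the smallest that its 252 splits can give (mean difference -0.15). The hypothesis came from the same comparison of the same animals, so neither p is an independent test of it. The median was also -0.17 with slide as a block. These values are consistent with a small shift of the group, which may differ between the materials or between the animals, and the test does not separate them.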
